A study of Oncorhynchus tshawytscha with 16 samples.

How the data were processed

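Liver RNA of natural subyearling fall Chinook salmon (Oncorhynchus tshawytscha) was measured on 16 one-colour arrays. Per the labels, 48 wild fish were collected, 12 in each of 4 groups, and equal amounts of liver RNA from 3 fish were pooled before labelling, which gave 4 pools and 4 arrays per group. Each array therefore holds its own 3 fish, so the spread between arrays of a group is the spread between pools and is smaller than the spread between single fish. The groups were parr rearing in the Snake River on 1 June, early migrants taken at Lower Granite Dam on the same river on 19 July, late migrants taken at that dam on 12 October, and non-migrants of the Clearwater River taken on 24 August. Per the labels' protocols, RNA was extracted with a column kit with DNase digestion, its integrity was checked on a Bioanalyzer, and it was labelled with Cy3 by a low-input amplification protocol.

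The deposited scanner files hold spot intensity on a linear scale. Per the file headers, the processed signal is the spot intensity after the background subtraction and adjustment of Agilent Feature Extraction 10.9.1.1 under the protocol GE1_107_Sep09, while the submitters' processing notes name version 10.10. The authors also deposited a table of log2 values, 1 column per array, whose scale and normalization are not given in the sources used here. Set against the scanner files by spot number, its columns followed the log2 of the raw median spot signal (r from 0.9954 to 0.9998 across spots) more closely than the log2 of the processed signal (r from 0.9476 to 0.967). Its medians were 4.37 to 4.43 and the maximum was 18.49 on every array, so it appears to be normalised between arrays, by a method that stays unknown. This table was used only as an alternative.

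From the scanner files, control spots and spots marked by the scanning software as outliers (4 to 133 per array) were left out, spots of 1 probe were averaged, and the processed signal was put on a log2 scale and expressed relative to the 75th percentile of its own array. All levels below are log2 values relative to that percentile. No spot was saturated. The arrays hold 43603 distinct probes, and a probe was tested if it was well above background on all 4 arrays of at least 1 group, which left 21880 probes (50.2%). Of these, 17504 were well above background on all 16 arrays. Between 45.6% and 54.8% of the spots of an array were well above background, and the 75th percentile of the processed signal lay between 38.4 and 64.2 intensity units. For arrays, the number of arrays limits the precision.

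The scanner files identify a probe by its design name and a sequence name only. None of the 41162 sequence names matched an accession or gene identifier in the Chinook gene table used here (0 of 41162 against 49936 genes), so no probe could be given a gene name. The gene lists fixed before the data were examined, which covered osmoregulation, hormone axes, lipid, sugar and amino acid metabolism, defence, the cell cycle and markers of other cell types, therefore could not be tested. The rule for naming genes, which asked for the largest differences past the threshold in each direction (with the 4 arrays of 1 group all above the 4 of the other in a pairwise comparison), was applied to probes in place of genes and reduced to at most 2 probes per direction and comparison.

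Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with all 16 arrays in 1 model of 4 group means (12 residual degrees of freedom and 3.07 prior degrees of freedom). Adjusted p-values are Benjamini-Hochberg values within each comparison, and a probe was called changed at an adjusted p under 0.05. All 6 pairwise comparisons, an overall F test, and the difference between the early and the late migrant minus non-migrant effects were tested. Where a probe was not well above background on some or all arrays of the lower group, the fold is given as a lower bound: on those arrays the higher of the probe's own level and the lowest level among probes well above background was used. Probes not well above background can lie above that lowest level, so it is no strict upper limit. Where the probe's own level was the higher on all of those arrays, the measured fold is given and no bound. The bounds are approximate and hold for the processed signal only. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

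The model was tested on simulated data over 21758 probes, with the spread of the real arrays and with known changes added to early migrants minus parr. It recovered 14.9% of 67 probes changed 1.5-fold, 43.3% of 67 changed 2-fold and 89.4% of 66 changed 4-fold. It made 4 false calls, and 0 calls in a comparison with no change. Far fewer probes were changed in the simulation than were called in the real comparison (3690). These values are therefore not read as recovery or false call rates of the real comparison. Nor are they read as rates for arrays that deviate together by slide.

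Per the file headers, the replicate number of the labels is the slide: each of the 4 slides holds 1 array of every group. All arrays have the same scan date, so no date could be fitted as a batch. Deviations from the group means were positively correlated between arrays of 1 slide (mean r across probes 0.236 over 24 pairs, of which 17 were over 0.1). Between slides the mean r was -0.079 over 72 pairs. Deviations from a group's own mean cancel out within the group, so a negative value between slides follows from the positive one within slides and is not separate evidence. The slide is a known batch that holds all groups, so comparisons are also given with the slide as a block and within each slide. Each group sits at its own place on the slide, the same place on all 4, so place on the slide and group cannot be told apart. Migrants were also taken at a dam and non-migrants at rearing sites, so site, date and migration status differ together.

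Alternatives fixed before the data were examined were quantile normalization, median centring, the authors' log2 values, no filter on dim probes, a filter asking for signal on all 16 arrays, the slide as a fixed or as a random block, an intensity trend in the variance, array weights, a model of the compared groups alone, a 2-fold minimum and leaving out each array. Background correction by normexp with an offset of 50 used the median spot signal, since the mean spot signal is not among the columns of the scanner files. That setting, a 75th percentile over probes above background on all arrays, scaling by 10 spike-in transcripts, and leaving out a whole slide were added after seeing the data.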

Results

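Livers of natural subyearling fall Chinook salmon were profiled in 4 groups of 12 fish, each measured as 4 pools of 3 fish on 1 array per pool. Subyearlings are fish in their first year, and parr are juveniles that are still rearing in fresh water. Parr from the Snake River (1 June) and non-migrants from the Clearwater River (24 August) were taken at rearing sites. Early migrants (19 July) and late migrants (12 October) were taken in the Snake River at Lower Granite Dam. The comparisons ask which liver transcripts differ between migrating and non-migrating fish, and between fish of the same status taken at different dates. The non-migrants of different dates also come from different rivers. Probes could not be given gene names from the gene table used here, so the text gives probe identifiers. Pools differ in site and date as well as in migration status.

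Of the 21880 probes tested, 6598 (30.2%) differed among the 4 groups in the overall test (limma F test, adjusted p under 0.05), and 8785 did with the slide as a block. Leaving out a whole slide gave 3584 to 4682. The first principal component held 35.3% of the variance over 21758 probes measured on every array and separated migrants from non-migrants. Its scores ran from 20.2 to 64.6 on the 8 migrant arrays and from -59.8 to -27.5 on the 8 non-migrant arrays. The second component (12.6%) did not separate the groups over all arrays, but on each of the 4 slides both later collections (August and October) scored above both earlier ones, an order noticed after the scores were seen. Profiles of different groups correlated best across probes where migration status was the same, with a mean r of 0.974 between early and late migrants and 0.965 between parr and Clearwater non-migrants. The lowest mean r was 0.940, between parr and late migrants. Within groups the mean r was 0.967 in parr, 0.978 in early migrants, 0.982 in late migrants and 0.974 in Clearwater non-migrants.

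**Figure D1:**
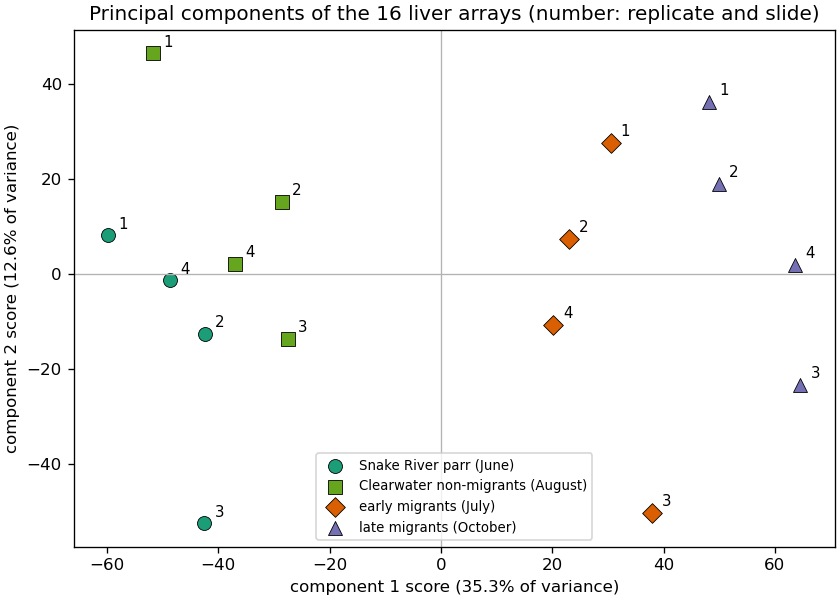
Scores of the 16 arrays on the first component (horizontal, 35.3% of the variance) and the second component (vertical, 12.6%), 1 point per array, with the replicate number, which is also the slide, beside it. The 8 migrant arrays lie at 20.2 or above on the first component and the 8 non-migrant arrays at -27.5 or below.

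The first comparison set early migrants in July against parr still rearing in June. In early migrants 1876 probes were higher and 1814 lower, together 3690 or 16.9% of those tested, and 1324 of them differed at least 2-fold. Probe A_05_P427347 was 16.8-fold higher in early migrants, with a level of 3.77 ± 0.23 (SD, n = 4) against -0.30 ± 1.05 in parr (log2 difference 4.07, SE 0.36, limma adjusted p = 1.21e-05). Probe A_05_P432982 was well above background on all 4 early migrant arrays and on none of the parr arrays, which makes it at least 26.5-fold higher (limma adjusted p = 9.2e-05). Its measured log2 difference of 5.7 was 3.3 with the authors' values and 1.73 with normexp, so this bound holds for the processed signal only. Probe A_05_P414837 stood at 10.78 ± 0.20 in parr and was 28.1-fold lower in early migrants, at 5.97 ± 0.39 (log2 difference -4.81, SE 0.56, adjusted p = 8.8e-05). Probe A_05_P433297 was lower in early migrants (-2.57 ± 1.1 against 2.73 ± 3.46 in parr, measured log2 difference -5.31, adjusted p = 0.00702), with 3 of 4 early migrant arrays above background. Parr replicate 2 stood at 7.78 and the other parr arrays at 0.08 to 1.99, and the probe is 1 of a set of 11 that were high on that array alone. Without it the log2 difference was -3.62 (adjusted p = 0.00142), so no fold is given for this probe. With all arrays, that call was lost with normexp background correction (adjusted p = 0.0611) and in a model of these 8 arrays alone (adjusted p = 0.0544). The differences of these 4 probes had the same direction on all 4 slides, which is fixed, since they were picked for groups that do not overlap. So did 3523 of the 3690, where it follows for the 3026 in which the groups did not overlap. Higher probes made up 50.8% of the calls, but 39.2% of 2203 with median centring and 10.2% of 6024 with scaling by the spike-ins, so the balance of directions depends on the scaling. A model of these 8 arrays alone called 2056 probes, and leaving out slide 1 gave 1770.

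The corresponding comparison later in the year set late migrants in October against Clearwater non-migrants in August. It gave 4958 changed probes (22.7%), 2552 higher and 2406 lower in late migrants, of which 1761 differed at least 2-fold. Probe A_05_P414837 had the largest negative difference, at -0.65 ± 1.65 in late migrants against 7.36 ± 0.44 in Clearwater non-migrants (257-fold, log2 difference -8.00, SE 0.56, limma adjusted p = 4.13e-07). Probe A_05_P454612 fell from 4.59 ± 0.80 in the non-migrants to -0.57 ± 1.13 in late migrants, a 35.7-fold difference (adjusted p = 8.39e-05). Probe A_05_P333752 was 16.4-fold higher in late migrants (1.19 ± 0.62 against -2.85 ± 0.33, adjusted p = 2.17e-05). Probe A_05_P436517 was not well above background on any array of the Clearwater non-migrants or the parr and was at least 4.68-fold higher in late migrants than in Clearwater non-migrants (adjusted p = 2.8e-07). On all 4 slides these differences had the same direction, which the rule for picking them fixes. So did 4840 of the 4958, where it follows for the 4467 in which the groups did not overlap. Leaving out slide 2 gave 2820 changed probes. Higher probes were 51.5% of the calls, 40.9% of 3011 with median centring and 17.6% of 5260 with scaling by the spike-ins.

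The early and late migrant effects share no arrays, so they can be set against each other directly. Across the 21880 probes their log2 differences had a correlation of r = 0.67 (probes are not independent replicates). Probes called higher in migrants in both comparisons numbered 988, where independent lists of the same lengths would share 218.8, and 1160 were called lower in both against 199.5. Both comparisons use the same estimate of each probe's spread, so their lists are not fully independent and these expected numbers may be too low. Only 18 probes were called in opposite directions. Of the 3690 probes called in the early comparison, 3381 (91.6%) had the same sign in the late one, against 75.7% of all probes tested.

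**Figure D2:**
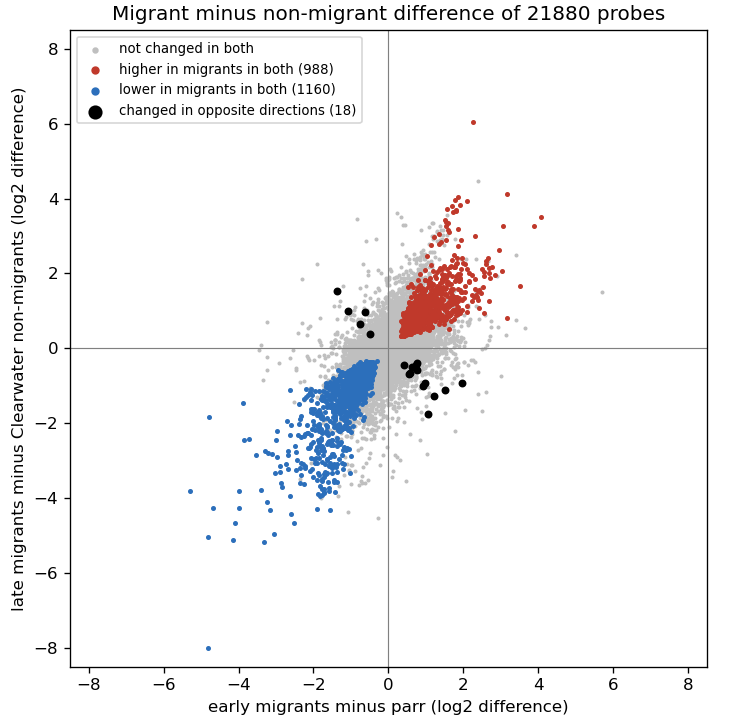
Each point is 1 of 21880 probes, with the log2 difference between early migrants and parr on the horizontal axis and between late migrants and Clearwater non-migrants on the vertical axis. Red points (988) were higher and blue points (1160) lower in migrants in both comparisons, and black points (18) changed in opposite directions.

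The difference between the early and the late migrant effect was tested for each probe, and 122 probes passed, 85 with the early effect above the late one and 37 below. With the slide as a block 248 passed. Probe A_05_P366832 stood at 10.44 ± 0.19 in parr and at 6.98 ± 0.16 in early migrants but at 7.40 ± 0.49 in late migrants and 7.44 ± 0.09 in Clearwater non-migrants. Its early effect lay below its late effect by a log2 difference of -3.42 (SE 0.28, limma adjusted p = 5.83e-05). Probes A_05_P287667 (measured log2 difference 4.17, SE 0.83, adjusted p = 0.0396), A_05_P254499 (3.13, SE 0.55, adjusted p = 0.0238) and A_05_P441367 (measured -3.38, SE 0.71, adjusted p = 0.0469) passed more narrowly. A_05_P287667 was above background on no parr array and on 3 of 4 late migrant arrays, and with the parr put at their upper bound the difference was 3.7. A_05_P441367 was above background on no Clearwater array and on 3 of 4 parr arrays, and with the Clearwater non-migrants put at their bound the difference was -2.69. Leaving out 1 array ended their calls in 12, 5 and 14 of 16 cases, leaving out any of the 4 slides ended all 3, and 4, 1 and 4 of the processing alternatives did (adjusted p up to 0.185, 0.0635 and 0.172). The differences of the 4 probes had the same sign on all 4 slides. Probes whose early effect lay above the late one made up 69.7% of the 122 calls and 48.0% of the 125 made with normexp. Leaving out a whole slide reduced the count to between 1 and 18, so the number of such probes rests on having all 4 slides.

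In the main model, fish of the same migration status had fewer changed probes. Clearwater non-migrants in August, set against parr in June, had 547 changed probes (2.5%), 314 higher and 233 lower, of which 296 differed at least 2-fold. With the slide as a block the count was 1099, and without replicate 4 of the parr it was 934. It was 101 in a model of these 8 arrays alone, 270 with median centring, 263 to 467 without another single array, and 72 without slide 1. Probe A_05_P489577 was 18.7-fold higher in Clearwater non-migrants (2.62 ± 0.57 against -1.60 ± 1.04, SE of the log2 difference 0.47, limma adjusted p = 0.000614). Probe A_05_P432982, not well above background in parr, was at least 4.37-fold higher in Clearwater non-migrants (adjusted p = 0.0261), a bound that holds for the processed signal only. The call was lost in 4 of the 8 cases in which 1 array was left out, with the authors' values (log2 difference 1.19, adjusted p = 0.148), with normexp (0.46, adjusted p = 0.43), without the filter on dim probes (adjusted p = 0.0587) and in a model of these 8 arrays alone (adjusted p = 0.0767). Probes A_05_P430277 (12.4-fold, adjusted p = 0.00321) and A_05_P491802 (11.3-fold, adjusted p = 0.00156) were lower in Clearwater non-migrants. Their levels were -1.37 ± 0.69 and -1.81 ± 0.73 there, against 2.26 ± 0.86 and 1.69 ± 0.68 in parr. All of these differences went the same way on all 4 slides, which the rule for picking them fixes. So did 538 of the 547, where it follows for the 519 in which the groups did not overlap. The call of A_05_P430277 was lost without slide 2 (adjusted p = 0.0587), and that of A_05_P432982 without any 1 of the 4 slides.

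Late migrants in October, set against early migrants taken at the same dam in July, had 310 changed probes (1.42%), 88 higher and 222 lower. With the slide as a block the count was 522 and with array weights 1143, but leaving out 1 array lowered it to as few as 145 and leaving out slide 4 to 37. Probe A_05_P414837 fell further, from 5.97 ± 0.39 to -0.65 ± 1.65, a 98-fold difference (log2 difference -6.61, SE 0.56, limma adjusted p = 0.000104). With the authors' values its log2 difference was -5.84 and with normexp -4.68. Probe A_05_P316702 was 7.03-fold lower in late migrants as measured (-2.42 ± 0.93 against 0.40 ± 0.61, adjusted p = 0.00563), with 2 of 4 late migrant arrays above background. Its measured log2 difference of -2.81 was -1.58 with the authors' values and -0.72 with normexp, and its call was lost without slide 1 (adjusted p = 0.065) and without slide 4 (0.0964). Probe A_05_P429502, above background on 1 of the 4 early migrant arrays, was at least 4.96-fold higher in late migrants (-0.71 ± 0.51 against -3.85 ± 1.31, adjusted p = 0.00406). Its measured log2 difference of 3.15 was 1.3 with the authors' values and 0.52 with normexp, and its call was lost without slide 4 (adjusted p = 0.0964). Probe A_05_P298442, not well above background in early migrants, was at least 6.24-fold higher in late migrants (adjusted p = 0.0452). Its call was lost whenever 1 of the 8 arrays was left out, and with the slide as a block (adjusted p = 0.0632), without the filter on dim probes (0.0952) and with scaling by the spike-ins (0.0617). It was also lost with the authors' values (log2 difference 1.72, adjusted p = 0.077) and normexp (0.59, adjusted p = 0.145), both under the bound. Higher probes were 28.4% of the calls, 14.9% of 148 with median centring, 39.6% of 381 with a percentile over detected probes, 41.9% of 396 with the authors' values and 48.7% of 419 with normexp, so the excess of lower probes depends on the normalization.

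Late migrants and parr were the last and first collections in the Snake River. Between them 6042 probes changed (27.6%), 3167 higher and 2875 lower in late migrants, and 2342 of them differed at least 2-fold. Leaving out slide 2 gave 3981. Probe A_05_P414837 was 2750-fold lower in late migrants (log2 difference -11.43, SE 0.56, limma adjusted p = 1.79e-08). On each slide its level was lower in late migrants than in parr, by log2 differences of -13.52 to -9.90. Late migrant replicate 3 stood lowest (-2.85), and without it the log2 differences of this probe were -10.69 from parr, -7.27 from Clearwater non-migrants and -5.88 from early migrants. Its step from early to late migrants, -6.61 with all arrays, was -5.84 with the authors' values and -4.68 with normexp. The size of its fold therefore depends on the processing. Probe A_05_P356102 was above background on all 4 parr arrays and on none of the late migrant arrays, at least 28.2-fold lower in late migrants (adjusted p = 2.22e-07). Probe A_05_P423387, with 1 of 4 parr arrays above background, was at least 19.7-fold higher in late migrants (1.54 ± 1.01 against -3.87 ± 1.33, adjusted p = 0.000372). Its measured log2 difference of 5.4 was 3.13 with the authors' values and 1.68 with normexp. Probe A_05_P327962 was at least 27.4-fold higher (3.41 ± 0.90 against -2.41 ± 3.33, adjusted p = 0.0352), with 2 of 4 parr arrays above background. Its call was lost in 6 of the 8 cases in which 1 array was left out. It was also lost in 3 of the 4 cases in which 1 slide was left out and with 1 processing alternative (adjusted p = 0.0662). The measured log2 difference of 5.82 for this probe was 4.93 without parr replicate 1 and 7.21 without parr replicate 4. Higher probes were 52.4% of the calls, 38.3% of 4401 with median centring and 18.4% of 6908 with scaling by the spike-ins. Of the probes tested, 298 were well above background on all late migrant arrays and on no parr array, and 43 showed the opposite. Of these, 209 and 42 were called. The parr arrays had fewer spots well above background (46.1% to 50.9%) than the late migrant arrays (51.4% to 54.7%), and the 298 and 43 are not corrected for that.

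Clearwater non-migrants differed from early migrants at 3348 probes (15.3%), 1594 higher and 1754 lower, with 1118 at least 2-fold. Probe A_05_P326717 was 22.1-fold higher in Clearwater non-migrants (3.11 ± 0.77 against -1.35 ± 0.90, limma adjusted p = 8.41e-05) and stood at 3.32 ± 0.79 in parr and -1.16 ± 0.51 in late migrants. Probe A_05_P475334 was not well above background on any early or late migrant array and was at least 7.29-fold higher in Clearwater non-migrants than in early migrants (adjusted p = 0.000758). Clearwater replicate 1 stood at 2 and the other Clearwater arrays at -1.35 to -0.58, so the size of this bound rests partly on that array. Probe A_05_P485612 was 15.7-fold lower in Clearwater non-migrants as measured (-2.87 ± 0.26 against 1.11 ± 0.71, adjusted p = 0.000204), with 2 of 4 Clearwater arrays above background. Its measured log2 difference of -3.97 was -2.31 with the authors' values and -1.1 with normexp. Probe A_05_P436517 was at least 3.65-fold lower (adjusted p = 3.63e-06). Higher probes were 47.6% of the calls, and 89.7% of 4881 with scaling by the spike-ins. Leaving out Clearwater replicate 1 or early migrant replicate 3 lowered the count to 2015 and 2133, median centring gave 1684, and leaving out slide 1 gave 1265.

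**Figure D3:**
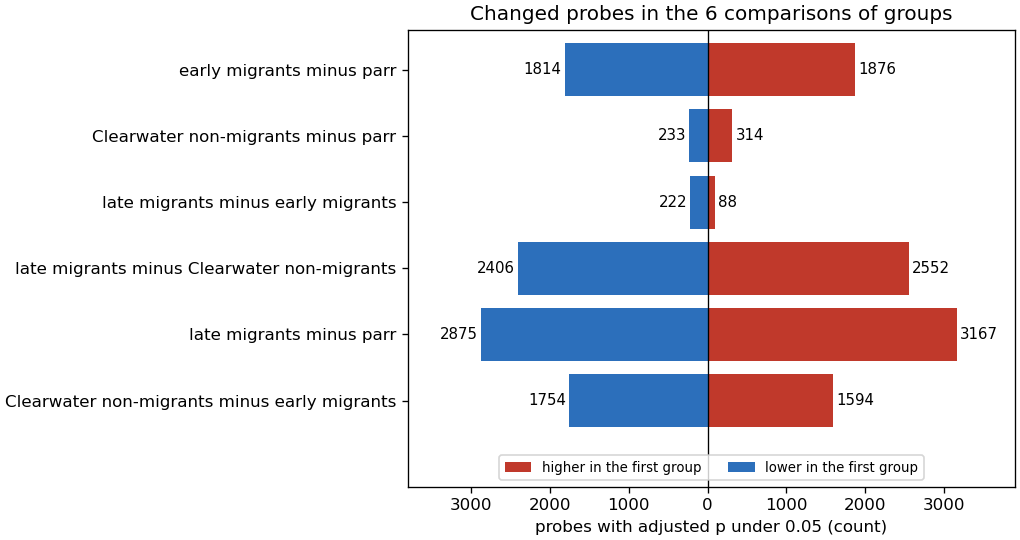
Number of probes with an adjusted p under 0.05 in each of the 6 comparisons (horizontal, counts from 0), with probes higher in the first-named group to the right and lower ones to the left. The comparisons of migrants with non-migrants reach 1594 to 3167 probes in a direction, and those within a migration status 88 to 314.

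**Figure D4:**
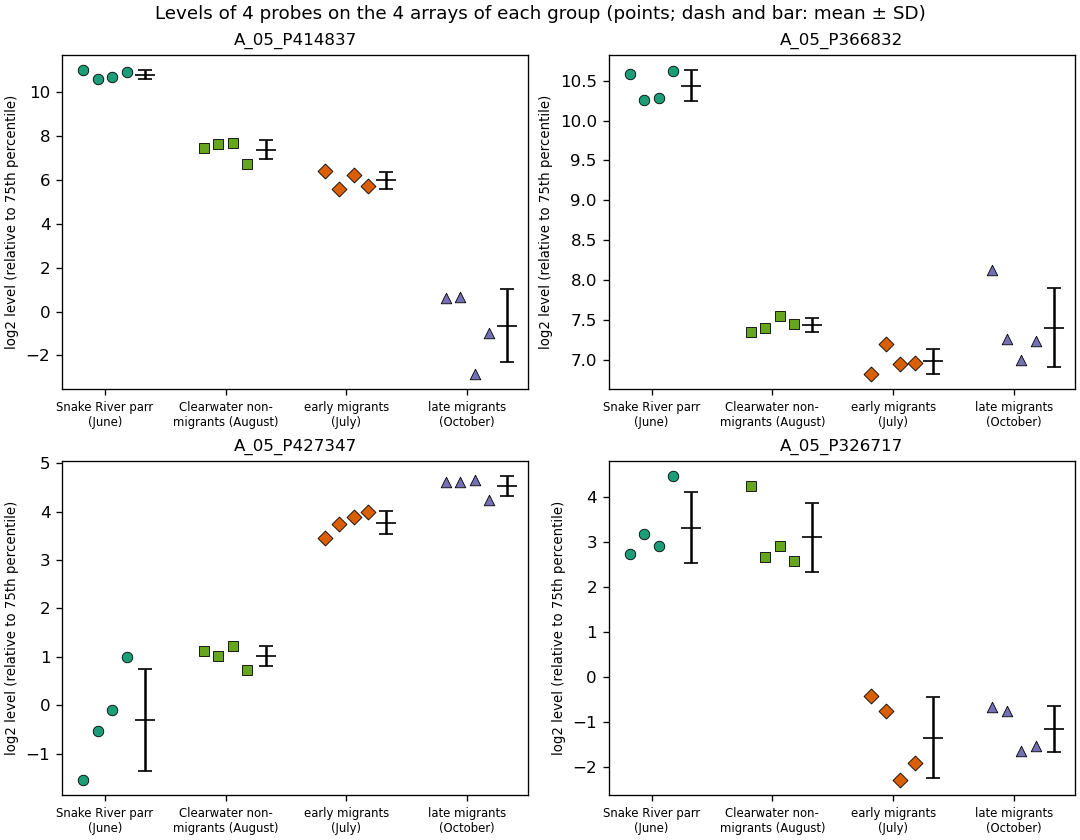
Log2 levels of 4 probes relative to the 75th percentile of the array (vertical), 1 point per array in each of the 4 groups, with the mean and SD of the group as a dash and bar (n = 4). A_05_P414837 falls from 10.78 in parr to -0.65 in late migrants, A_05_P366832 lies at 10.44 in parr and between 6.98 and 7.44 in the other groups, A_05_P427347 is higher and A_05_P326717 lower in both groups of migrants.

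The scaling used above sets the 75th percentile of every array equal. Relative to it, the 10 spike-in transcripts, RNAs of known sequence that are added to every sample at labelling, had log2 levels that were higher in migrants by 0.131 to 0.400. Scaling by the spike-ins therefore moved the median log2 difference over all probes tested from 0.04 to -0.31 for early migrants minus parr, from 0.05 to -0.21 for late migrants minus Clearwater non-migrants, from 0.05 to -0.26 for late migrants minus parr and from -0.03 to 0.27 for Clearwater non-migrants minus early migrants. Median centring moved the median for late migrants minus parr from 0.05 to -0.07. The differences given above are relative to the bulk of the probes. The sizes of the 28 differences of named probes moved with the processing. With the authors' values the folds of 24 of them were smaller by over 1.5 times, and with normexp those of 26 were.

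Where 2 tested probes carried the same sequence name, they mostly moved together. In 1252 such pairs, the brighter probe was called in 244 for early migrants minus parr, and the other had the same direction in 215 of these (88.1%) and was called the opposite way in 1. For late migrants minus Clearwater non-migrants the direction was the same in 264 of 303 pairs (87.1%), with 3 called the opposite way. In the other pairwise comparisons the share with the same direction was between 86.3% and 100%.

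Some probes varied far more between arrays of 1 group than between groups. A set of 20 probes that moved together had mean levels of 4.77 and 7.04 on Clearwater replicates 1 and 3, but -0.71 and -1.07 on replicates 2 and 4. On the late migrant arrays the set stood at 2.21 in replicate 2 and between -1.84 and -0.84 in the others, and on the parr and early migrant arrays it lay between 0.24 and 2.20. The brightest, A_05_P248904, ranged from 2.83 to 11 among the Clearwater non-migrants. A set of 11 probes, with A_05_P433297 among them, was high on parr replicate 2 alone (6.81, against -0.74 to -0.01 on the other arrays), and a set of 10 was low on Clearwater replicate 2 alone (-4.39, against 3.62 to 4.13). The probes of these 2 smaller sets lay at neighbouring spots, with median distances of 8.0 and 8.5 spots against 162.4 and 163.1 for random probes, so they are not read as differences between pools.

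**Figure D5:**
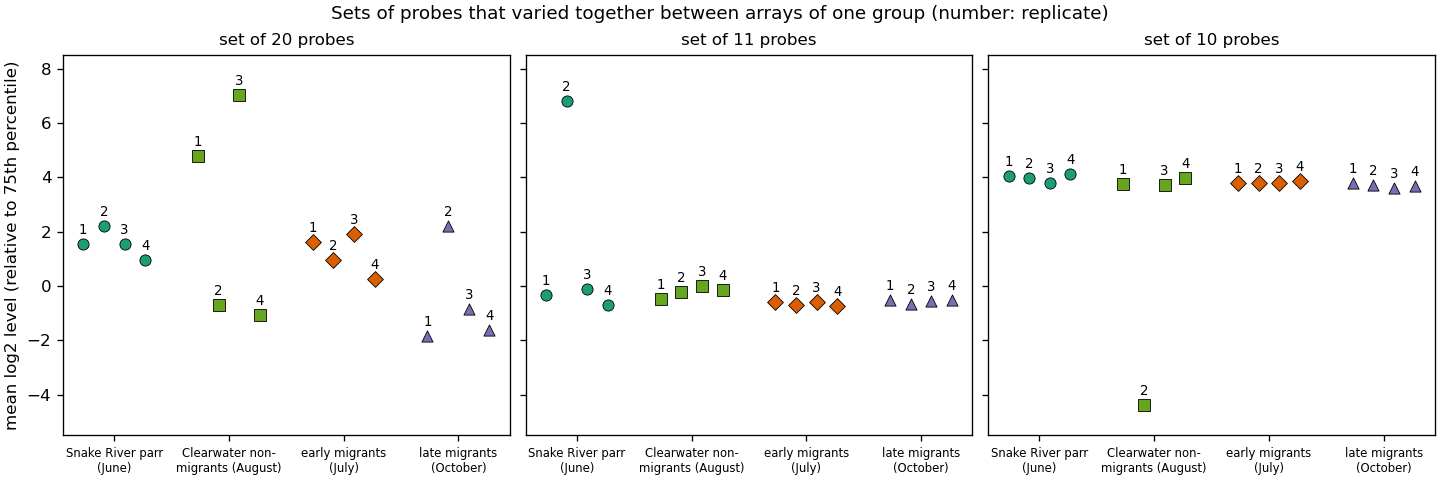
Mean log2 level of 3 sets of probes relative to the 75th percentile of the array (vertical), 1 point per array in the 4 groups, with the replicate number above each point. The set of 20 probes spans -1.07 to 7.04 within the Clearwater non-migrants, while the sets of 11 and 10 probes depart on 1 array each, at 6.81 and -4.39, and lie at neighbouring spots.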

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

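Regroupings of the arrays, the dependence of the slide effect on brightness and the distances between spots had their bounds written before the results were seen. The tests of the correlation between the migrant effects, and of dates, and the regroupings within slides, were chosen only after the result was seen.

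Other groupings of the same arrays did not give counts as large as the real ones. For the 6 pairwise comparisons, the 35 ways to divide the 8 arrays into 4 and 4 were run, and in each comparison 1 of the 35, the real one, reached its count. The real count and the highest of the others were 3690 and 29 for early migrants minus parr, 547 and 84 for Clearwater non-migrants minus parr, 310 and 3 for late minus early migrants, 4958 and 2 for late migrants minus Clearwater non-migrants, 6042 and 1 for late migrants minus parr, and 3348 and 0 for Clearwater non-migrants minus early migrants. Among the 8 divisions that part all 4 slides, the highest other count was 0 in 5 comparisons and 1 for late migrants minus parr, but 8 divisions are too few for a share under 0.05. For the difference between the 2 migrant effects, 1 of 100 regroupings (99 drawn and the real one) reached 122, and the highest other was 12. For the overall test, 1 of 100 reached 6598, and the highest other was 185. Where the arrays are treated as exchangeable, each share of the 35 or 100 groupings is under 0.05. Deviations shared by arrays of 1 slide go against that treatment, so these regroupings alone do not exclude chance. Those for the difference between the 2 migrant effects mixed early with late migrants and parr with Clearwater non-migrants. They test whether those groups are alike, so they do not decide whether the 2 effects are equal. With groups exchanged only within slides, 1 of 100 regroupings (99 drawn and the real one) reached 6598 in the overall test, and the highest other was 1648. For the difference between the migrant effects 1 of 100 reached 122, and the highest other was 64, with the same limit on what was tested.

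The difference between the early and the late collections in how migrants compared with non-migrants was tested directly, and 122 probes were set apart for a closer look. Site, date and place on the slide differ along with migration, and the same contrast sets July and August against June and October, so no source is assigned. The named ones had measured differences of 4.17 (A_05_P287667), 3.13 (A_05_P254499), -3.42 (A_05_P366832) and -3.38 (A_05_P441367). In the first and the last of these, 1 group was not above background on any array, the parr and the Clearwater non-migrants, and with that group at its bound the differences were 3.7 and -2.69. For A_05_P366832 the parr arrays, which were the earliest collection, stood apart from all others.

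Single arrays stood far from the other 3 of their group in 7 cases by Dixon's test. Chance gives about 1 in 20 groups, and the cases were 1 of 28 for measures of whole arrays and 6 of 92 for levels of named probes. Clearwater replicate 2 had 19 outlier spots, where the other arrays of its group had 4 to 6. The level of A_05_P427347 was 4.23 on late migrant replicate 4, against 4.61 to 4.66. For A_05_P489577 it was 1.66 on early migrant replicate 1, against 0.21 to 0.45, and for A_05_P491802 it was -2.15 on early migrant replicate 3, against -3.47 to -3.38. On Clearwater replicate 1, A_05_P429502 stood at -4.42, against -3.95 to -3.89. On parr replicate 2, A_05_P436517 stood at -3.95, against -5.02 to -4.91, and A_05_P441367 at -0.89, against -3.19 to -2.85. A_05_P429502 was above background on no Clearwater array, A_05_P436517 on no parr array and A_05_P491802 on 1 of the 4 early migrant arrays. Their levels in those groups are therefore near background.

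The separation of migrants from non-migrants took up the first principal component. A constant shift of whole arrays, from scaling or from a place effect common to all spots, leaves the correlation across probes of the early and late migrant effects unchanged. These effects share no arrays, and their correlation was 0.671 over probes measured on every array. In 324 pairs of divisions that balance migrants and non-migrants the highest absolute value was 0.564 and the median 0.0967, which argues against such a shift as the whole source. A steady trend with time of year would order the groups by date. On the first component the July migrants (20.2 to 37.9) instead lay above the August non-migrants (-51.7 to -27.5), which argues against such a trend as its whole source. Further, 3 probes differed one way in all 4 comparisons of the later with the earlier collections, against 1405 for migrants against non-migrants. That count needs calls in late minus early migrants and in Clearwater non-migrants minus parr, which had few (310 and 547). It therefore does not measure effects of date, and averaged over these collections 826 probes differed. Migration itself, the capture site (dam or rearing site) and the river stay open. So do date other than as a steady trend, and effects of the place on the slide that differ between probes. The design confounds these, so the pattern may be biological but the tests do not separate them.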

How the results depend on the processing

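Scaling by the spike-ins, the percentile over detected probes, normexp on median signals and leaving out whole slides were chosen after seeing the data. The 28 differences of named probes kept their direction in all 343 values from processing alternatives, of which 21, from 7 of the 28, lost the threshold. The filters, the slide blocks, the intensity trend and the model of the compared groups leave the difference itself unchanged. Direction could therefore be tested only by the other normalizations and the array weights. Their sizes did not hold. With the authors' values 24 and with normexp 26 of the 28 were smaller by over 1.5 times as folds. The 7 pairwise ones with no array above background in the lower group all fell under their bound in both. The authors' values follow the raw spot signal and normexp adds an offset. The log2 difference of A_05_P436517 (late minus Clearwater) went from 4.12 to 1.17 and 0.41, and that of A_05_P356102 from -6.31 to -3.16 and -1.57. With 1 array left out 49 of 256 values, from 6 of the 28, lost the threshold, and with 1 slide left out 27 of 112, from 9. There were 0 reversals, but for the pairwise differences this was fixed, since they were picked for groups that do not overlap. Counts are given below in the order early minus parr, Clearwater minus parr, late minus early, late minus Clearwater, late minus parr, Clearwater minus early, and the difference of the migrant effects, where each moved by over 1.5 times. Except where stated, the cause was not tested.

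Median centring gave 2203, 270, 148, 3011 and, for Clearwater minus early, 1684, with 35 for the difference and 4286 in the overall test. Scaling by the spike-ins gave 6024, 260 and 184, and 63 for the difference. Without the filter on dim probes, which doubles the probes adjusted for, Clearwater minus parr gave 259, late minus early 180 and the difference 31 (87.1% of them higher). A 2-fold minimum, which can only remove probes, gave 1324, 296, 163, 1761, 2342 and 1118. A model of the compared groups alone, with fewer arrays for the spread, gave 2056 for early minus parr and 101 for Clearwater minus parr. Array weights gave 873 for Clearwater minus parr, 1143 for late minus early and 409 for the difference. With the replicate block (the slide) these 3 were 1099, 522 and 248, and with the slide as a random block (correlation 0.221) 1169, 642 and 340. The block ended 1 call among the named probes (A_05_P298442), and of the main calls 3659 of 3690, 545 of 547, 302 of 310 and 4909 of 4958 were also made with it. Quantile normalization, the authors' values, normexp, the intensity trend, the percentile over detected probes and the filter on all 16 arrays moved no count by over 1.5 times.

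Leaving out 1 array gave 2704 to 4085, 263 to 934, 145 to 241, 3583 to 4322, 4798 to 6251, 2015 to 2728 and 27 to 198, and 5375 to 7479 in the overall test. Fewer arrays lower the power, but leaving out parr replicate 4 raised every count that uses parr, to 4085, 934, 6251, 198 and 7479. Moves of over 1.5 times came for Clearwater minus parr from parr replicates 1 (294), 2 (351), 3 (330) and 4 (934) and Clearwater replicates 1 (274), 2 (267) and 3 (263). For late minus early they came from early replicates 2 (193) and 4 (147) and late replicates 1 (197) and 4 (145), and for Clearwater minus early from early replicate 3 (2133) and Clearwater replicate 1 (2015). For the difference they came from parr replicates 2 (55), 3 (64) and 4 (198), early replicates 1 (39), 2 (49) and 4 (27), late replicates 3 (70) and 4 (33) and Clearwater replicates 1 (49), 2 (65), 3 (77) and 4 (54). Leaving out a whole slide gave 1770 to 2788, 72 to 474, 37 to 137, 2820 to 3244, 3981 to 4545, 1265 to 2270 and 1 to 18, and 3584 to 4682 in the overall test.

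Not run were the gene lists, since no sequence name matched the gene table used, a scan date block, since all arrays share 1 date, normexp on the mean spot signal, and a 2-fold minimum for the overall test, which has no single fold. Signal over background limits the comparisons to 21880 of 43603 probes.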

Other observations

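Which groups shared a level was counted in ways chosen after seeing the data. Averaged over the pairs of groups, migrants differed from non-migrants at 7550 probes, the August and October collections from those of June and July at 826, and the remaining pairing (July and August against June and October) at 122. Of the mean square of these 3 contrasts over all probes, less the part due to sampling, migrants against non-migrants held 76.9%, the later against the earlier collections 15.5% and the remaining pairing 7.59%. The first contrast also sets dam against rearing sites and places on the slide against each other, so its share is not one of migration alone. The Clearwater non-migrants come from another river and are among the later collections, so the share of that contrast is not one of date alone. All 4 comparisons of a migrant with a non-migrant group called the same direction for 644 probes higher and 761 lower in migrants. Probes that differed one way from all 3 other groups numbered 96 higher and 196 lower in parr, 29 and 10 in early migrants, 64 and 173 in late migrants, and 31 and 60 in Clearwater non-migrants.

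Arrays of 1 slide deviated from their group means together. The bound for brightness was written before its result was seen, and the test of shared numbers after. Across probes, these deviations had mean r of 0.322, 0.110, 0.414 and 0.099 for slides 1 to 4, and 1 of 13824 ways to number the arrays within groups, the real one, gave a mean as high as 0.236 (highest other 0.215, exact permutation p = 7.23e-05, the smallest possible). This is consistent with shared processing of a slide, though replicate number and slide coincide, so handling by number before hybridization cannot be told apart from the slide. An effect that depends on probe brightness was argued against, since probe brightness, in 10 classes, explained a median over slides of 2.68% of their mean deviations. No biological explanation was tested.

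Sets of probes that varied together within groups were looked for among the 77 probes with a within-group SD of at least 1.5 that were measured on every array. The bounds on spot distances were written before the result was seen, and those on slopes and shared slides after. The 11 probes high on parr replicate 2 and the 10 low on Clearwater replicate 2 lay closer together on the array than any of 10000 random sets (median spot distances of 8.0 and 8.5 against 162.4 and 163.1, share 1e-04 in each, the smallest possible), in line with local defects of those arrays. Probe A_05_P433297 is 1 of the 11, and its log2 difference for early migrants minus parr was -5.31 with parr replicate 2 and -3.62 without it. The set of 20 probes lay no closer than random probes (158.4 against 160.2, share 0.463), which argues against a local defect, and a shared slide was not decided (exact permutation p = 0.437). In this set 95% of the probes moved by between 0.5 and 1.5 log2 units per unit of the others (median slope 1.07). Of the 20 probes 19 had been picked for their spread and correlation, which nearly fixes such slopes, so they do not decide whether RNA of 1 other source in varying share or genes regulated together could be behind the set.

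Parr replicate 4 deviated most from its group. It had 345 probes over 4-fold from the mean of the other parr arrays, where the other 15 arrays had 35 to 187, and 133 outlier spots, where they had 4 to 63. The median within-group SD was 0.324 in parr and 0.247 without that array, against 0.233 to 0.254 in the other groups.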
